A study of Homo sapiens with 1733 samples.

How the data were processed

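Single cells of the H1 embryonic stem cell line were sorted by DCX at days 26, 54, 100 and 125 of a ventral forebrain differentiation, with doublets and dead cells excluded at the sort by scatter and DAPI per the labels. Polyadenylated RNA was amplified by SmartSeq2 with 22 PCR cycles, made into Nextera XT libraries and sequenced as 50-base paired-end reads. How DCX was read in the sort is not given in the sources used here. The authors aligned the reads with Bowtie to hg19 and quantified them with RSEM, without stating versions. The deposited expected counts (RSEM estimates of reads per gene) were used for sums and tests, and the deposited TPM (transcripts-per-million) for alternatives. Of the nonzero expected counts 63.9% were exactly whole, so sums were rounded before the tests, and each cell's TPM added up to between 999999 and 1000001. The tables held 23045 genes and 1733 cells, while the design text states 1732, and every column was matched to a labelled cell. No cell had the same counts as another, and no gene took more than 4.66% of all counts.

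The groups held 245, 352, 316 and 80 DCX+ cells and 231, 233, 203 and 73 DCX− cells at days 26, 54, 100 and 125. They came from 3, 5, 4 and 1 plates of DCX+ cells and 3, 4, 3 and 1 plates of DCX− cells, with 17 to 88 cells a plate, and 3 plates with 192 cells carried a letter suffix. Median total counts per cell were 1096002, 1127083, 1226629 and 984180 in DCX+ and 1436354, 1296520, 1376948 and 1729466 in DCX−. Median genes detected were 6106, 5856, 5624 and 5369 in DCX+ and 6778, 6562, 7089 and 6723 in DCX−. The sums came to 311471300, 444965186, 399461454 and 86169138 counts for DCX+ and 357036427, 377048498, 317536591 and 125804215 for DCX−. No cell was removed. The labels name no separate cultures, so each gate and day was 1 sample and neither cells nor plates were treated as replicates.

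Gene tests used edgeR 4.0.16 in R 4.3.3 on the summed counts, with TMM factors, genes kept by filterByExpr (minimum count 10, minimum total 15), glmQLFit without robust estimation, glmQLFTest and a Benjamini-Hochberg threshold of 0.05. The gates were compared over 8 sums with harvest day as a block (3 residual degrees of freedom). After removal of the gate means, the sums of the 2 gates of a day correlated across 17671 genes at r = 0.382, 0.170, 0.215 and 0.149 for days 26, 54, 100 and 125, against -0.231 to 0.124 for sums of different days. Genes are not independent replicates, and these values served only to check the pairing. Both gates of a day also share the culture age, so the values cannot tell a shared harvest from a shared age. With the gate means removed, lower values between different days follow in part from higher ones within a day. Trends over log2 of the day were fitted in DCX+, in DCX− and in the inhibitory-neuron-like DCX+ cells (4 sums and 2 residual degrees of freedom each), and the difference of slopes was tested over all 8 sums. Slopes are given as the fitted log2 change from day 26 to day 125, and for genes with no reads on a day the CPM (counts-per-million, after TMM) are given by day. The SE of a gene was the size of its log2 change divided by the square root of the F value of the quasi-likelihood test. It is not the standard error of the differences of the single days.

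On simulated data with 50 genes changed at each size, the gate test found 4%, 74%, 84% and 90% of genes changed by 1, 2, 3 and 4 on the log2 scale. The trend tests found 0%, 12%, 40% and 70% in DCX+, 0%, 14%, 50% and 66% in DCX− and 0%, 18%, 34% and 62% in the inhibitory-neuron-like cells, and the test of slopes found 0% at each size. Unchanged genes called numbered 3 in the gate test, 1 in the inhibitory-neuron-like cells and 0 in the others.

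Before the data were examined, 23 gene lists, the cell type markers, the tests and the rule for named genes were fixed. The lists covered cell cycle, radial glia, Notch and proneural, hedgehog targets, ventral forebrain transcription factors, pan-neuronal, GABAergic, interneuron subtype, cholinergic and basal forebrain, excitatory cortical, synapse and ion channel, astrocyte, oligodendrocyte lineage, diencephalon to hindbrain, pluripotency, mesenchymal to blood, choroid plexus and ependyma, immediate early and heat shock, hypoxia and glycolysis, unfolded protein response, MHC and interferon, and cytosolic ribosomal proteins. The mitochondrially encoded list could not be tested, because 0 of its 10 names occur in the tables, which left 22. Older symbols were matched for LAMP5, NSG1 and NSG2. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, with fry and an estimated correlation beside it. The list test in the inhibitory-neuron-like cells was added after the data were examined. Several lists share genes, for example HES1 and HES5.

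The rule named DCX and the 10 highest and 10 lowest log2 fold changes among genes past the threshold with the same sign on 4 days and a mean of at least 16 CPM, leaving out unannotated loci. For trends it took the 10 steepest each way of those past the threshold, or with none the 10 largest by size. From each list it took up to 2 members at each end, and for single days the 5 largest differences each way at a mean of at least 32 CPM with 1 CPM added. Subtype markers were named when detected in at least 5% of cells on any day.

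For cell classes, counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1 (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15), giving 18 clusters. A cluster took the name of the class with the best score, the general neuron class left aside. The score had to be at least 0.5, and at least 3 of the class's markers had to reach 50 CPM. Where the general neuron class scored higher than a best class that was not neuronal, the best-scoring inhibitory, excitatory or cholinergic neuron class took its place. Where none of these had 3 markers at that level, the name was neuron. A class with most markers among the cluster's top 10 genes went first, and oligodendrocyte precursors and oligodendrocytes were joined. The markers were fixed beforehand, but this naming rule was written after a first look at the clusters, and of its 2 versions the second was kept after the cluster tables were seen. A cluster stayed unnamed when its top 10 genes held more markers of another class, the general neuron class excepted, as in the cluster with LHX8 among its leading genes. The score minimum left unnamed a cluster led by stress genes, with 15 and 5 DCX+ cells at days 100 and 125 and 1, 19 and 35 DCX− cells at days 54, 100 and 125. No doublet caller was run.

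Shares carry exact Clopper-Pearson 95% intervals (scipy 1.17.1), and differences between the gates were tested over the 4 days by an exact two-sided sign-flip permutation. For subtype markers each cell was thinned to 600000 reads, a depth reached by 92.2% of DCX+ cells, and a share of 0 was given the limit that 3 counts allow. Numbers were handled with numpy 2.4.6, pandas 2.3.3 and anndata 0.12.19, and figures were drawn with matplotlib 3.10.9.

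Alternatives were RLE factors, no low-count filter, DESeq2 1.42.0, limma-trend on mean CPM and mean TPM of the cells with 1 added, omission of the lettered plates, omission of each day, no block, untransformed day, an estimated correlation for lists, Leiden resolutions 0.5 and 2, clustering of TPM or of 4000 genes, and other detection limits for markers (10 reads, TPM of 1, unthinned reads, all DCX+ cells). Leaving out cells with under 50% of their group's median genes removed no cell and tested nothing. Added after the data were examined were omission of the stress-gene cluster, omission of the lettered DCX− plate of day 54, clustering without the marker genes, and the estimated correlation in the inhibitory-neuron-like cells. Genome coordinates are not printed, because the annotation at hand (GRCh38) differs from the build of the counts.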

Results

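Polyadenylated RNA was profiled by SmartSeq2, a plate-based full-length protocol, in 1733 single cells derived from H1, an established human embryonic stem cell line. The cultures had passed through cortical induction with SMAD inhibitors, ventral patterning with Shh and purmorphamine from day 10, and neural differentiation with BDNF, GDNF, NT3 and cAMP from day 24. Cells were harvested at days 26, 54, 100 and 125 and sorted into a DCX+ and a DCX− fraction. DCX is doublecortin, a microtubule-binding protein of migrating young neurons. The question, as the series title gives it, was which cell types the protocol produced over time. The 8 groups of gate and day came from 24 plates, and each plate held cells of 1 group. Total counts per cell ranged from 205118 to 8679216 (median 1263473), and 4007 to 10045 genes were detected per cell (median 6263). Summed over the cells of a group, the counts came to between 86169138 and 444965186. The labels named no separate cultures, so each gate and day was treated as 1 sample, and the 4 harvest days were the replicates of the gate comparison. The p-values of the gate comparison therefore measured the spread of the gate difference between these harvests. Each harvest had another culture age, so this spread can hold changes with age as well as technical differences. The p-values of the trends measured the spread of the harvests around a fitted line. On day 125 each gate came from 1 plate, so plate and group could not be told apart there. Intervals and detection limits cover counting error only, because reads without molecular identifiers are not independent molecules.

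Inhibitory-neuron-like cells, which carried GAD1, GAD2, DLX and LHX6 transcripts, made up most of the DCX+ fraction in the clustering used here, although at day 26 this depended on the settings. Their share was 76.7% at day 26 (95% Clopper-Pearson interval 70.9 to 81.9), 97.7% at day 54 (95.6 to 99.01), 85.1% at day 100 (80.7 to 88.9) and 78.8% at day 125 (68.2 to 87.1). At day 26 the share was 77.6% at a finer clustering and 73.1% without the lettered plates, but 0.408% at a coarser clustering, 36.3% with TPM, 40.4% with 4000 genes and 36.3% without the marker genes. In these 4 settings the missing cells stayed unnamed or took another class, while the shares of days 54, 100 and 125 lay between 78.8% and 98.01%. In the DCX− fraction radial-glia-like cells made up 77.9% of cells at day 26 and 49.4% at day 54. Astrocyte-like cells were not found there at days 26 and 54 (0 cells, which allows up to 1.30% and 1.29%, although a coarser clustering placed 1.29% and one without the marker genes 0.429% there at day 54) and made up 60.1% at day 100 (53.01 to 66.9) and 43.8% at day 125 (32.2 to 55.9). Averaged over the 4 days, the share of inhibitory-neuron-like cells was 78.3 percentage points higher in DCX+ than in DCX− (SD 3.90, n = 4 days, higher on 4 of 4 days). By an exact two-sided sign-flip permutation test over the 4 days this gave p = 0.13, the smallest value that 4 pairs allow, so no share could pass 0.05.

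The progenitor classes lay mainly in the DCX− fraction. The mean difference in percentage points, DCX+ minus DCX−, was -36.5 for radial-glia-like cells (SD 33.04) and -7.57 for dividing-progenitor-like cells (SD 7.002), each lower in DCX+ on 4 of 4 days (exact permutation p = 0.13). They were -23.2 without day 26 and -4.89 without day 54, respectively. Among DCX− cells the radial-glia-like share stood at 19.2% at day 100 and 1.37% at day 125, and dividing cells at 11.3%, 16.7%, 3.94% and 1.37% over the 4 days. Neurogenic progenitor-like cells, which carried DLL1 and DLL3 transcripts, were 8.23%, 18.5%, 1.97% and 0% of DCX− cells and 0% to 1.27% of DCX+ cells (mean difference -6.43, SD 8.16, lower on 3 of 4 days, exact permutation p = 0.25). This difference was -2.70 without day 54 and turned to 2.57 when the cells were clustered without the marker genes, and with TPM no cluster took this name. Astrocyte-like cells reached 4.43% and 7.50% of DCX+ cells at days 100 and 125 (mean difference -23.0, SD 27.7, exact permutation p = 0.5). Without day 100 this difference was -12.1. At a finer clustering it was -14.5, and a mesenchymal-like cluster of 40 cells with COL1A2, LUM and COL3A1 came apart, with 12.8% and 13.7% of DCX− cells at days 100 and 125. Oligodendrocyte-lineage-like cells, with MBP, GPR17 and PDGFRA, were 2.53% and 6.25% of DCX+ cells and 0.4926% and 2.74% of DCX− cells at days 100 and 125. None was found at days 26 and 54 (mean difference 1.39, SD 1.71, exact permutation p = 0.5). This difference was 0.680 without day 125 and became -2.18 at a finer clustering. No cluster took this name at a coarser clustering or without the marker genes.

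Clusters left without a name held 20.8% of DCX+ cells at day 26, 0% at day 54, 4.75% at day 100 and 7.50% at day 125, against 0%, 0.429%, 9.36% and 47.9% (36.1 to 59.96) of DCX− cells. The mean difference was -6.17 (SD 25.4, exact permutation p = 0.63) and turned to 5.26 without day 125. At day 26 these were 51 DCX+ cells with LHX8 among their leading genes, and they were 0%, 23.5% and 40% of the cells of the 3 plates. The others, apart from 1 DCX+ cell of day 125, belonged to a cluster led by the heat shock and stress genes HSPA6, CRYAB, GDF15, ATF3 and DDIT3. Inhibitory-neuron-like cells were 15.02% of DCX− cells at day 54. They came largely from 1 plate with a letter suffix, on which they were 57.1% of cells, and their share was 1.69% without the lettered plates. At a coarser clustering no cluster was named radial-glia-like, and the mean difference of the inhibitory-neuron-like share was 59.9 points.

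**Figure D1:**
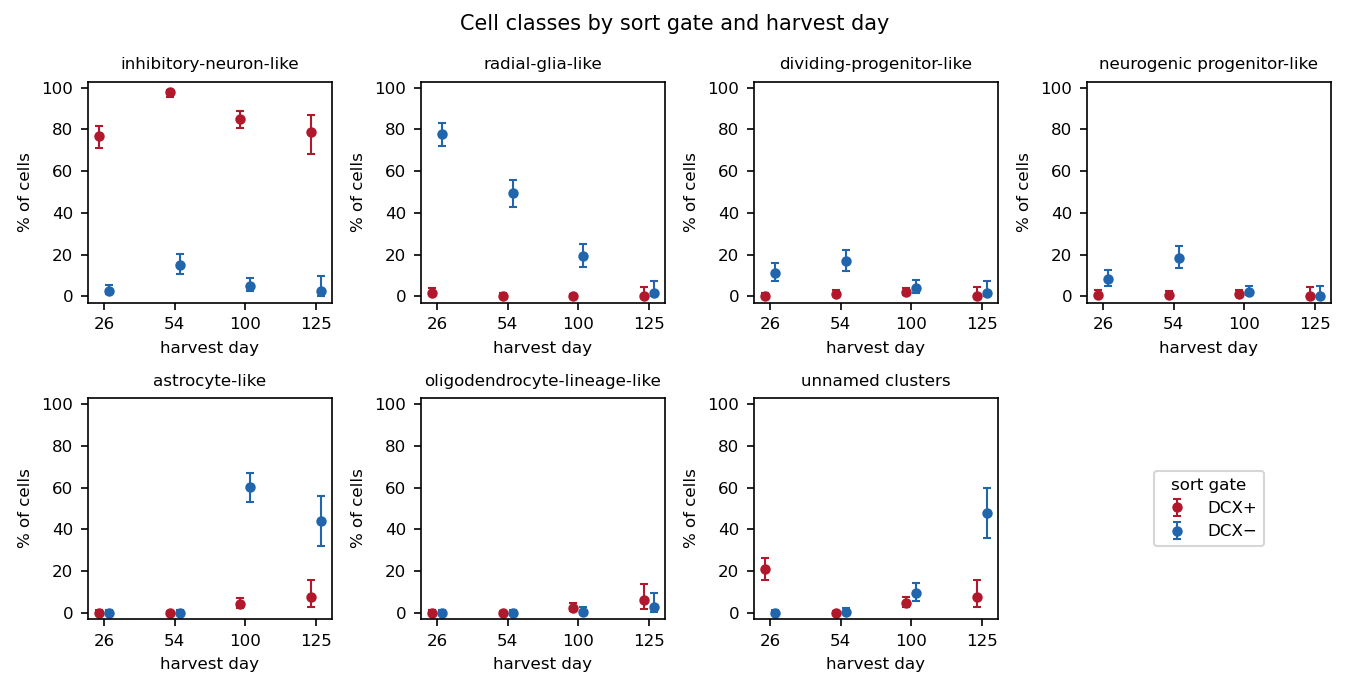
Share of cells (y axis, %) in each cell class by harvest day (x axis) for the DCX+ (red) and DCX− (blue) fractions, with 95% Clopper-Pearson intervals that cover counting error only. Inhibitory-neuron-like cells lie between 76.7% and 97.7% of DCX+ cells, and radial-glia-like cells give way to astrocyte-like cells and unnamed clusters among DCX− cells after day 54.

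The DCX+ fraction carried more SST, NXPH1 and GAD1 transcripts and fewer MCM10 and EDNRB transcripts than the DCX− fraction. DCX, the sorting gene and so no finding, was 15.7-fold higher (log2 fold change 3.98 ± 0.55, SE, n = 4 days, adjusted p = 0.0133, higher on 4 of 4 days). The SE of each gene was derived from the F value of its test. It stood at 801, 760, 773 and 744 CPM (counts-per-million) in DCX+ against 71.8, 126.2, 42.1 and 13.2 CPM in DCX− at days 26, 54, 100 and 125. SST, the peptide somatostatin, was 27.4-fold higher (log2 4.78 ± 0.50, adjusted p = 0.0101). NXPH1, a secreted neurexin ligand, was 21.2-fold higher (log2 4.41 ± 0.32, adjusted p = 0.00715) and GAD1, which makes GABA from glutamate, 17.03-fold (log2 4.09 ± 0.48, adjusted p = 0.0107). In the other direction MCM10, a DNA replication factor, was 28.7-fold lower in DCX+ (log2 -4.84 ± 0.47, adjusted p = 0.00715) and EDNRB, the endothelin receptor B, 30.9-fold lower (log2 -4.95 ± 0.91, adjusted p = 0.0235). Of 17671 genes tested with edgeR's quasi-likelihood test, 2352 passed a Benjamini-Hochberg adjusted p of 0.05, 1075 of them higher and 1277 lower in DCX+.

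Among the largest increases with the same direction on all 4 days and a mean of at least 16 CPM were also VSTM2A, a membrane protein of the immunoglobulin family (22.6-fold), and NSG2, an endosomal protein of neurons listed as HMP19 (22.2-fold). They also held GALNT14, which starts O-linked glycosylation (20.3-fold), PHACTR3, an actin and phosphatase regulator (19.03-fold), and GABRB2, a GABA-A receptor subunit (17.5-fold, log2 4.13 ± 0.96). CRHBP, which binds corticotropin-releasing hormone, was at 0.0316, 47.9, 113.2 and 62.8 CPM in DCX+ and at 0, 0.650, 4.44 and 0 CPM in DCX−. The largest decreases included ANXA1, an annexin (29.1-fold), SFRP2, a secreted Wnt regulator (28.2-fold), FBN2, a fibrillin (26.9-fold), and PMP22, a myelin protein (25.5-fold, log2 -4.67 ± 0.96). A further 4 of the largest decreases had no reads in DCX+ at 1 day: GPC3, a glypican, stood at 7.92, 0.0307, 5.03 and 0 CPM in DCX+ against 175.4, 221.8, 49.8 and 95.6 CPM in DCX−. E2F7, a repressor of the cell cycle, stood at 0.249 to 4.50 CPM on the other 3 days against 33.7 to 57.8 CPM. GPNMB, a lysosomal glycoprotein, reached 241.8 CPM in DCX− at day 125 against 2.70 CPM, but at day 54 it stood at 0.0108 CPM against 0. It was a leading gene of the stress-gene cluster, which held 35 of the 73 DCX− cells of day 125. RPE65, a retinoid isomerase, reached 89.3 CPM in DCX− at day 100 against 6.44 CPM.

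**Figure D2:**
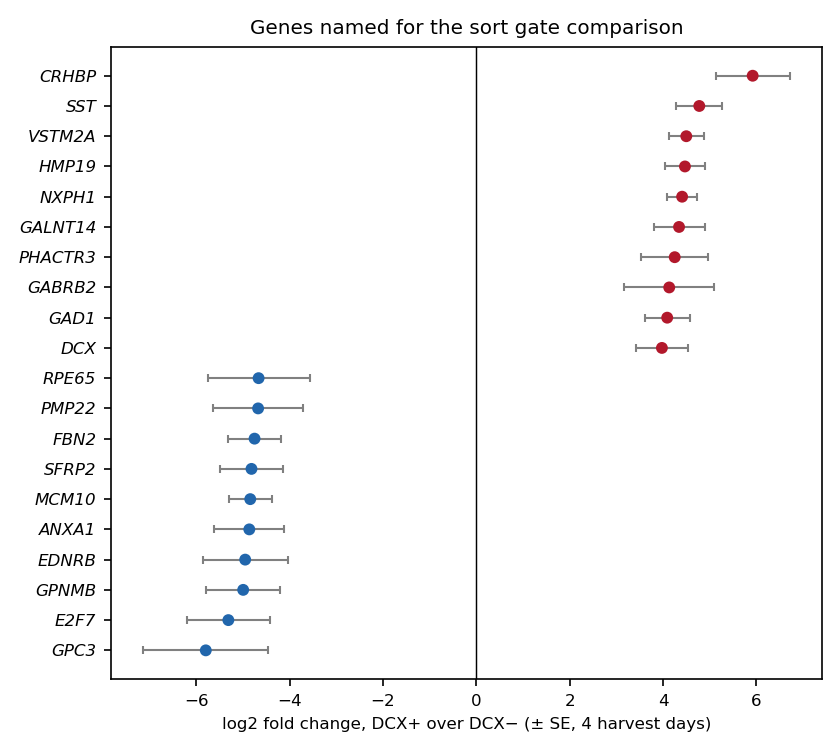
Log2 fold changes (x axis) of the 20 genes with the largest changes between the sort gates, DCX+ over DCX−. They were taken from annotated genes past the threshold with the same sign on 4 days and a mean of at least 16 CPM. Bars are ± 1 SE, derived from the F value of the test and not from the differences of the single days. The 10 genes higher in DCX+ run from 3.98 (DCX) to 5.92 (CRHBP) and the 10 lower ones from -4.66 (RPE65) to -5.79 (GPC3), and CRHBP, GPC3, E2F7, GPNMB and RPE65 had no reads in 1 fraction on at least 1 day.

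Cell-cycle genes and progenitor genes were lower in DCX+ cells as groups. Of 24 cell-cycle genes measured, 20 passed the test and all 20 were lower, 23 when adjusted over the list alone (camera adjusted p = 1.47e-24, and adjusted p = 0.224 with an estimated correlation). MKI67, a proliferation antigen, was 18.4-fold lower (log2 -4.20 ± 0.46). Also lower were NUSAP1, a spindle protein, 15.7-fold, PCNA 3.36-fold and the helicase subunit MCM7 3.03-fold. Of 17 radial glia and progenitor genes 10 were lower and none higher, 15 when adjusted over the list alone (camera adjusted p = 2.07e-12, and adjusted p = 0.224 with an estimated correlation). They included TNC, an extracellular matrix protein (23.03-fold), HES1, a Notch effector (28.2-fold), PAX6 (5.78-fold) and SOX9 (4.37-fold). Of 13 Notch and proneural genes 7 were lower, 8 when adjusted over the list alone (camera adjusted p = 0.000229, and adjusted p = 0.335 with an estimated correlation). Among them were the ligand JAG1 (6.05-fold), HES5 (17.7-fold) and HES4 (3.18-fold). Of 14 astrocyte genes 4 were lower, 10 when adjusted over the list alone (camera adjusted p = 0.000595, and adjusted p = 0.352 with an estimated correlation): CD44 (20.9-fold), ALDH1L1 (12.2-fold), APOE (4.56-fold) and the bicarbonate transporter SLC4A4 (4.03-fold). Dividing, radial-glia-like and astrocyte-like cells lay mainly in the DCX− fraction, as given above.

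Neuronal, GABAergic, synaptic and interneuron genes were higher in DCX+ cells as groups. Of 20 pan-neuronal genes, the sorting gene DCX included, 15 were higher and none lower, 17 when adjusted over the list alone (camera adjusted p = 2.12e-29, and adjusted p = 0.121 with an estimated correlation). They ran from NSG2 down to the adhesion molecule NCAM1 (3.19-fold) and the RNA-binding protein ELAVL3 (2.61-fold). Of 35 synapse and ion channel genes 20 were higher and none lower, 26 when adjusted over the list alone (camera adjusted p = 5.44e-19, and adjusted p = 0.153 with an estimated correlation). They included the vesicle and release proteins STX1A (4.59-fold) and VAMP2 (3.19-fold) beside SYN2, which had no reads in DCX− at day 125 and 15.9 CPM in DCX+. Of 11 GABAergic genes 6 were higher, 9 when adjusted over the list alone (camera adjusted p = 9.51e-11, and adjusted p = 0.153 with an estimated correlation). They included DLX5 (5.83-fold) and DLX6 (4.89-fold) beside GAD1. Of 22 ventral forebrain transcription factors 7 were higher and 1 lower, 11 and 2 when adjusted over the list alone (camera adjusted p = 2.89e-06, and adjusted p = 0.291 with an estimated correlation). LHX6, which marks interneurons of the medial ganglionic eminence, was 14.4-fold higher (log2 3.85 ± 0.53), LHX8 9.56-fold and SATB1 3.45-fold, and GSX2, a progenitor factor, was 5.997-fold lower. Of 20 interneuron subtype markers 7 were higher and 1 lower, 11 and 1 when adjusted over the list alone (camera adjusted p = 2.21e-05, and adjusted p = 0.121 with an estimated correlation). RELN, the secreted protein reelin, was 7.67-fold higher, the calcium-binding SCGN reached 46.02 CPM in DCX+ at day 100 against 0.0640 CPM, and the chemokine CXCL14 was 9.82-fold lower. LHX8 was also the only member of 10 cholinergic and basal forebrain genes to pass (camera adjusted p = 0.261). None of 15 oligodendrocyte-lineage genes passed (camera adjusted p = 0.977), with MBP 5.33-fold higher (adjusted p = 0.174) and PDGFRA 5.10-fold lower (adjusted p = 0.229).

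The calls of genes by sort gate differed with the harvests kept and with the method. The 2352 genes were 13.3% of those tested, against 6.01%, 3.44%, 1.12% and 8.30% without day 26, 54, 100 and 125, 8.96% without harvest day as a block and 25.7% with DESeq2. Of the 2352 genes between 2332 and 2352 could be tested in each setting tried, all of them with their direction kept.

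Within single days, where 1 sum per gate allowed no test, the genes with the largest differences were not the same from day to day. At day 26 GAD1 stood at 329.3 CPM in DCX+ against 5.33 CPM in DCX−, the synaptic protein SNAP25 at 358.2 against 7.25 and SEZ6L at 134.5 against 2.34. The transcription factor MYT1L stood at 88.1 against 1.26 and the netrin receptor DCC at 525.9 against 13.3. ANXA1, CKAP2L, KIF20A, NUSAP1 and IQGAP3 lay lower in DCX+. At day 54 EGR2, CORT (a peptide related to somatostatin), NXPH1, BMP3 and SST led, SST with 3820 CPM against 255.3 CPM. SLC1A3, VCAM1, GPC3, SPARCL1 and S1PR1 were lowest. SLC1A3, a glial glutamate transporter, had 0.264 CPM in DCX+ and 548.4 CPM in DCX−. At day 100 CRABP1, which binds retinoic acid, had 695.1 CPM against 5.26 CPM, ahead of BMP3, CORT, IGF1 and CRHBP. SLCO1C1, BMPR1B, EDNRB, IFI44L and the water channel AQP4 (23.4 against 451.4 CPM) were lowest. At day 125 CRABP1 (728.4 against 2.26 CPM) was followed by GABRB2, CAMKV, SLITRK3 and SST. DLK1 (1.04 against 777.3 CPM), COL1A2, HSPA6, LUM and COL1A1 were lowest, the last 4 with no reads in DCX+.

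Over the days the DCX+ fraction had more NFIA and NFIX and less ISL1 and SLITRK6, although no gene passed the trend test. NFIA, a nuclear factor I transcription factor, stood at 0.127, 36.9, 310.3 and 534.8 CPM at days 26, 54, 100 and 125. NFIX stood at 0.0168, 0.247, 24.9 and 79.1 CPM. ISL1, a transcription factor of ventral neurons, went from 77.2 to 6.83, 0.00242 and 0.0906 CPM. SLITRK6, a synaptic adhesion protein, went from 163.8 to 14.1, 1.96 and 0 CPM. The other genes with the largest slopes by size included PMP2 (0.0804, 0.806, 96.6 and 292.8 CPM), TNC (0.00335, 0.354, 25.5 and 74.5) and AQP4 (0.519, 0.756, 22.6 and 263.4). They also included GFAP (0.352, 0.142, 8.33 and 135.6), MLC1 (0.312, 0.770, 19.8 and 55.4) and BCAN (1.54, 4.08, 121.9 and 310.5). With edgeR 0 of 16600 genes passed, against 2548 at an unadjusted p under 0.05, 1462 with DESeq2 and 0 with limma, and leaving out day 54 gave 14. In simulated data the test found 70% of genes changed by 4 on the log2 scale and 12% of those changed by 2.

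As lists in the DCX+ fraction, astrocyte genes were higher at later days (camera adjusted p = 3.04e-11, and adjusted p = 0.424 with an estimated correlation), with 12 of 14 genes higher when adjusted over the list alone. Astrocyte-like cells were 4.43% and 7.50% of this fraction at days 100 and 125 and none was found earlier. Synapse and ion channel genes were also higher (camera adjusted p = 4.02e-07, and adjusted p = 0.424 with an estimated correlation, 6 of 35 adjusted over the list alone). The GABA-A receptor subunit GABRA2 stood at 1.57, 131.7, 215.1 and 228.99 CPM and the sodium channel SCN1A at 1.26, 6.79, 18.5 and 46.97 CPM. Interneuron subtype markers were higher (camera adjusted p = 0.000383, and adjusted p = 0.424 with an estimated correlation, 0 of 20 adjusted over the list alone), for example LAMP5 at 1.81, 0.384, 21.8 and 51.1 CPM. Oligodendrocyte-lineage genes (camera adjusted p = 0.00111, 3 higher and 1 lower of 15 adjusted over the list alone) and radial glia genes (camera adjusted p = 0.00311, 4 higher and 2 lower of 17) were higher with adjusted p = 0.461 and adjusted p = 0.477 with an estimated correlation. Ventral forebrain transcription factors were lower (camera adjusted p = 3.54e-05, and adjusted p = 0.424 with an estimated correlation, 1 higher and 11 lower of 22 adjusted over the list alone). LHX8 stood at 678.2, 31.2, 12.4 and 13.1 CPM and SP8 at 36.9, 0.754, 0.852 and 0 CPM, against 105.8, 290.1, 427.2 and 442.0 CPM for ZEB2. Cholinergic and basal forebrain genes (camera adjusted p = 0.00244, 1 higher and 3 lower of 9) and pan-neuronal genes (camera adjusted p = 0.00586, 0 higher and 5 lower of 20 adjusted over the list alone) were lower with adjusted p = 0.424 and adjusted p = 0.461 with an estimated correlation. TUBB3, a neuronal tubulin, stood at 2638, 1689, 632 and 589 CPM. Cell-cycle (camera adjusted p = 0.911), Notch and proneural (camera adjusted p = 0.207) and GABAergic genes (camera adjusted p = 0.911) were not called, although within the last list ERBB4 stood at 5.82, 257.4, 405.3 and 616.2 CPM.

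In the sums of the DCX− fraction NDUFA4L2, a mitochondrial protein induced by low oxygen, rose, and SHISA2, COL2A1, SALL4 and the unannotated transcript JA040725 fell. The cells of this fraction went from mostly radial-glia-like at day 26 to mostly astrocyte-like cells and the stress-gene cluster at day 125. SHISA2 and COL2A1 were leading genes of a radial-glia-like cluster. That cluster held mainly DCX− cells of day 26 and no cell of day 100 or day 125. The fall of these genes therefore cannot be told apart from the loss of that cluster, and a change within a cell class was not tested. NDUFA4L2 changed by 9.64 ± 0.48 on the log2 scale from day 26 to day 125 (SE, 4 days, edgeR adjusted p = 0.0291), from 0.197 to 5.24, 70.7 and 171.1 CPM. SHISA2, an inhibitor of Wnt and FGF receptor maturation, changed by -5.95 ± 0.38 (adjusted p = 0.0318), from 218.6 to 25.7, 6.94 and 3.07 CPM. COL2A1, a cartilage and notochord collagen, went from 95.5 to 5.18, 0.293 and 0 CPM (adjusted p = 0.0291). SALL4, a stem cell transcription factor, went from 53.2 to 1.09, 0.110 and 0 CPM and JA040725 from 760.6 to 195.2, 71.4 and 42.9 CPM (both adjusted p = 0.0318). The last 2 were named after their values were seen. These were the only 5 of 16930 genes to pass with edgeR, against 3578 at an unadjusted p under 0.05, 2410 with DESeq2 and 0 with limma. With the day untransformed there was 1 call, which was not among the 5. Without day 26 there were 7 calls, none of them among the 5, and without day 100 or day 125 there were 0, while 54 genes passed without the cells of the stress-gene cluster.

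As lists in the DCX− fraction, astrocyte genes were higher at later days and cell-cycle genes lower (both camera adjusted p = 1.41e-21, and adjusted p = 0.453 with an estimated correlation). All 14 astrocyte genes were higher and 21 of 24 cell-cycle genes lower when adjusted over the list alone. AQP4 stood at 0.439, 1.19, 466.5 and 773.4 CPM and AGT, angiotensinogen, at 0.112, 0.0791, 49.5 and 84.1 CPM. The mitotic kinase AURKB stood at 108.3, 64.7, 18.2 and 1.30 CPM. Radial glia genes went both ways (camera adjusted p = 0.453, 2 higher and 3 lower of 17 adjusted over the list alone), with HOPX, a gene of outer radial glia, at 0.294, 39.4, 465.8 and 93.9 CPM and HES5 at 19.9, 11.7, 2.61 and 1.10 CPM. Synapse and ion channel genes were higher (camera adjusted p = 0.0062, 2 of 33 adjusted over the list alone) and ventral forebrain transcription factors lower (camera adjusted p = 0.0235, 1 of 22), each with adjusted p = 0.613 with an estimated correlation. Cholinergic and basal forebrain genes were lower (camera adjusted p = 0.0386, and adjusted p = 0.453 with an estimated correlation, 1 higher and 1 lower of 9 adjusted over the list alone), with ACHE, acetylcholinesterase, at 0.260, 2.94, 5.27 and 36.6 CPM and LHX8 at 29.4, 15.8, 0.881 and 1.35 CPM. Notch and proneural (camera adjusted p = 0.241), pan-neuronal (0.626), GABAergic (0.464), subtype (0.160) and oligodendrocyte-lineage genes (0.155) were not called.

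The change over the days differed between the gates for CRABP1. In DCX+ CRABP1 stood at 10.6, 114.98, 695.1 and 728.4 CPM at days 26, 54, 100 and 125 and in DCX− at 33.9, 13.9, 5.26 and 2.26 CPM. The change differed by 10.08 ± 0.45 on the log2 scale (SE, 4 days, edgeR adjusted p = 0.0318). It was the only 1 of 17671 genes to pass, against 1858 at an unadjusted p under 0.05, 624 with DESeq2 and 0 with limma, and in simulated data this test found 0% of the genes changed by 4 on the log2 scale. The call was lost without day 26, 100 or 125 and without the lettered plates, and 3 genes passed without day 54. CRABP1 was a leading gene of cluster 12, an inhibitory-neuron-like cluster with 0, 1, 79 and 29 DCX+ cells at days 26, 54, 100 and 125. The higher CRABP1 level in DCX+ after day 54 therefore cannot be told apart from the appearance of that cluster. A change within the cluster was not tested.

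**Figure D3:**
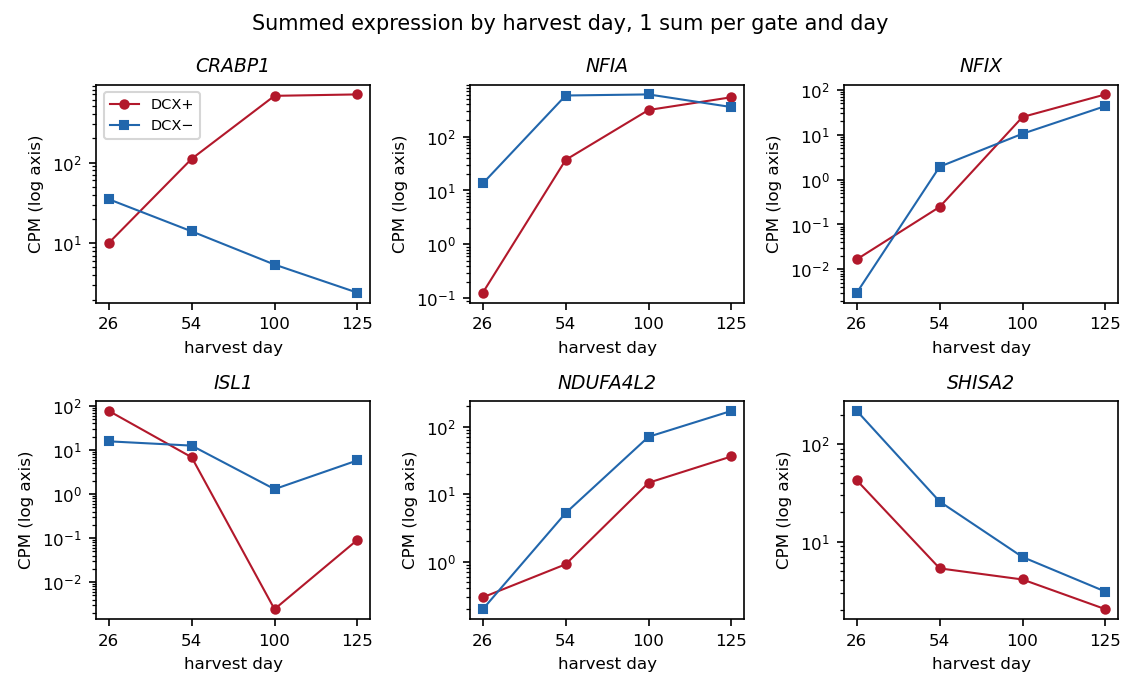
Counts-per-million (y axis, log scale) of 6 genes by harvest day (x axis) in the summed DCX+ (red circles) and DCX− (blue squares) cells, 1 sum per point, so no error bar is drawn. CRABP1 stands at 10.6 to 728.4 CPM in DCX+ and at 33.9 down to 2.26 CPM in DCX−, NDUFA4L2 reaches 171.1 CPM and SHISA2 3.07 CPM in DCX−, and NFIA, NFIX and ISL1 passed no trend test.

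Restricted to the inhibitory-neuron-like DCX+ cells, synaptic genes were higher and genes of early ventral and cholinergic identity lower at later days as lists. The clusters that held most of the class differed between days 26, 54 and 100, while days 100 and 125 shared clusters 12 and 16. They were clusters 3 and 4 at day 26, 7, 10, 11 and 13 at day 54, 12, 14 and 16 at day 100 and 12 and 16 at day 125. Of 35 synapse and ion channel genes 9 were higher when adjusted over the list alone (camera adjusted p = 1.31e-11, and adjusted p = 0.283 with an estimated correlation). GABRA2 stood at 1.45, 133.5, 243.4 and 295.4 CPM. Cholinergic and basal forebrain genes were lower (camera adjusted p = 1.68e-06, and adjusted p = 0.283 with an estimated correlation, 4 of 8 adjusted over the list alone), with ISL1 at 81.3, 6.94, 0 and 0.119 CPM. Ventral forebrain transcription factors were lower (camera adjusted p = 3.15e-06, and adjusted p = 0.283 with an estimated correlation, 1 higher and 12 lower of 22 adjusted over the list alone), with SP8 at 41.1, 0.766, 0.731 and 0 CPM against 102.2, 289.01, 480.2 and 475.3 CPM for ZEB2. Notch and proneural genes were lower (camera adjusted p = 0.00023, and adjusted p = 0.283 with an estimated correlation, 2 of 13 adjusted over the list alone), with the ligand DLL1 at 277.7, 51.4, 36.6 and 18.5 CPM. Subtype markers (camera adjusted p = 9.5e-05, 3 of 20 adjusted over the list alone) and astrocyte genes (camera adjusted p = 0.000237, 4 of 11) were higher, both with adjusted p = 0.356 with an estimated correlation, and here GFAP stood at 0.310, 0.139, 3.39 and 10.96 CPM.

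No gene passed with edgeR in the test of genes by day in inhibitory-neuron-like cells (0 of 16200, against 2626 at an unadjusted p under 0.05, 1500 with DESeq2 and 0 with limma, and 1.01% of genes without day 54). The genes with the largest slopes by size, none of which passed, were again NFIX (0.0224, 0.251, 27.01 and 93.8 CPM), NFIA (0.0718, 32.3, 309.4 and 517.5) and PMP2 (0.0852, 0.819, 13 and 67.04). On the high side there were also THRB, a thyroid hormone receptor (0, 1.05, 53.8 and 16.6), COL19A1 (0.0314, 2.17, 46.96 and 18.2), the angiopoietin ANGPT2 (1.36, 12.3, 242.5 and 190.01), STARD13 (0.0359, 13.2, 63 and 114.99) and the potassium channel KCNJ2 (0.938, 1.04, 61.97 and 88.8). On the low side were ISL1 and the glypican GPC4 (91.01, 4.57, 0.378 and 1.68). Pan-neuronal (camera adjusted p = 0.139), GABAergic (0.587), cell-cycle (0.131), radial glia (0.462), oligodendrocyte-lineage (0.462) and MHC and interferon genes (0.219) were not called.

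Somatostatin was the most widely detected interneuron peptide among inhibitory-neuron-like DCX+ cells. After thinning each cell to 600000 reads, SST was detected in 13.2% of cells at day 26 (interval 8.44 to 19.3), 89.8% at day 54 (85.99 to 92.9), 77.4% at day 100 (71.6 to 82.5) and 66.1% at day 125 (52.99 to 77.7). The unthinned values were 12.8%, 91.9%, 78.8% and 68.3%. NXPH1 was detected in 29.3%, 74.4%, 67.9% and 85.5% of cells and CORT in 4.19%, 33.3%, 25.9% and 11.3%. The calcium-binding CALB2 was detected in 2.40%, 14.2%, 29.2% and 29.03% (unthinned 2.13%, 15.1%, 29.4% and 28.6%). LAMP5 reached 24.2% at day 125 (14.2 to 36.7) from 2.40%, 2.16% and 11.1%, and CHODL 24.2% from 9.58%, 6.79% and 12.8%. TAC3, the precursor of neurokinin B, reached 19.4% (10.4 to 31.4) from 7.19%, 1.23% and 9.05%. CRHBP (0.599%, 13.6%, 20.6% and 9.68%), NPY (0.599%, 14.8%, 12.8% and 4.84%), RELN (0.599%, 13.3%, 5.76% and 4.84%), TAC1 (10.8%, 15.4%, 9.05% and 3.23%) and CALB1 (1.20%, 8.95%, 9.88% and 6.45%) were highest at day 54 or 100. SCGN was detected in 18.6%, 0.309%, 13.6% and 1.61% of cells. CXCL14 was detected in 8.38%, 1.54% and 2.88% of cells and in 0 of 62 at day 125, which allows up to 4.84%.

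NOS1 was detected in 44.9%, 39.8%, 34.98% and 37.1% of cells, but at 10 or more reads in at most 1.61%, so its shares rest almost wholly on cells with under 10 reads. VIP, PVALB, CCK, CRH and PENK stayed under 5% of cells on every day, and HTR3A was found in 0 cells on all 4 days, which allows up to 1.80%, 0.926%, 1.23% and 4.84%. There was 1 sample per day and no test, and 21, 20, 26 and 1 shallower cells of days 26, 54, 100 and 125 were left out by the thinning.

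**Figure D4:**
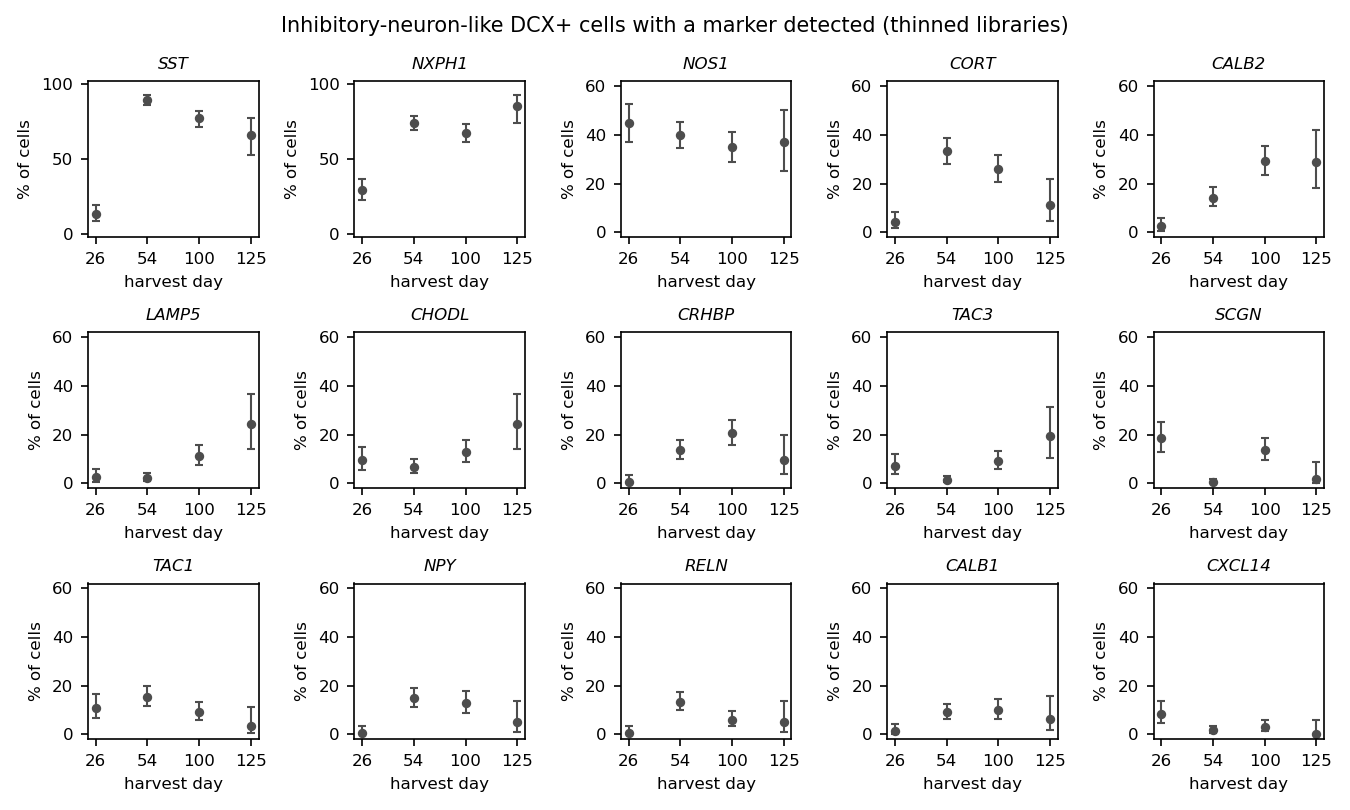
Share of inhibitory-neuron-like DCX+ cells (y axis, %) with each of 15 subtype markers detected by harvest day (x axis), in libraries thinned to 600000 reads, with 95% Clopper-Pearson intervals that cover counting error only. SST goes from 13.2% at day 26 to 89.8% at day 54 and 66.1% at day 125, while CALB2, LAMP5 and TAC3 have their higher shares at days 100 and 125.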

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

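The tests of explanations in this part, the count of other splits included, were chosen after the results were seen. The test of slopes was set before for all genes, and CRABP1 was not singled out beforehand but is given as its only call. A value far from the others was looked for in 31 sets of values and found in 8, all of them sets of plates. The sets were the 4 to 5 plates of a group or the differences of a class share between the gates over the 4 days. Chance gives about 1 in 20 (5%) for values with a normal spread. That rate does not hold for shares of few cells, and in 2 of the 8 sets a single cell stood against plates at 0.

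Inhibitory-neuron-like cells made up 57.1% of the cells on plate 25, a lettered plate of the DCX− gate at day 54, against 0% to 5.88% on the other 3 plates of that group. A plate of the DCX+ gate under a wrong label is argued against by its progenitor-like cells, 42.9% of the plate (interval 29.7 to 56.8) against at most 6.52% (upper limit 17.9%) on a DCX+ plate of that day. Neurons without DCX transcript are argued against as well, since 3.13% of its 32 inhibitory-neuron-like cells had no DCX read. Cells of both gates on 1 plate stay a candidate explanation: the median DCX level of those 32 cells was 643.4 CPM, within the quartiles of the DCX+ gate of that day (416.1 to 981.1 CPM). No other biological explanation was tested for this plate.

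The cluster led by HSPA6, DDIT3, ATF3 and GDF15 held 35 of the 73 DCX− cells of day 125, a share of 47.9%. Shallow libraries are argued against, since these cells had a median total of 112.3% of that of the other cells on the plate. Their median of genes detected was lower, 6256 against 6797. Handling of that plate cannot account for the cells of this cluster elsewhere, such as 14.7% (7.28 to 25.4) of a DCX− plate of day 100. That share is lower, so it cannot decide whether handling caused the excess on the plate of day 125. Day 125 and the handling of its plate cannot be told apart, because the gate has 1 plate on that day. Whether the age of the culture is involved stays untested.

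Plate 25 also had a mean DCX level of 442.4 CPM, against 74.97 to 101.7 CPM on the other 3 DCX− plates of day 54, and the lowest median of genes detected, 6066.5 against 6765 to 6836. Plate 19 of the same group, the smallest with 17 cells, had a median total of 5687626 counts against 902114 to 1517083. Neurogenic progenitor-like cells were 30.3% of plate 13 of that group against 11.8% to 13.1%. A single cell of an unnamed cluster made up 1.19% of plate 15 of that group, against 0% of its other plates. Plate 17 of DCX+ at day 100 had a median of 6421 genes detected against 5246 to 5350. A single radial-glia-like cell made up 2.17% of plate 18 of DCX+ at day 54, against 0% of its other plates. The change of CRABP1 over the days differed between the gates by 10.08 on the log2 scale in the test of the difference itself.

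For the 2352 genes that passed between the gates, 8 splits of the 8 sums part both gates on all 4 days, and 1 of them, the real one, gave a count as large, with 0 genes as the highest of the others. These splits are too few for a share under 0.05.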

How the results depend on the processing

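Of the values of single named genes under the alternatives, 86.7% kept their direction and their side of the threshold, 6.04% fell short of it and 3.40% newly passed. A further 3.52% changed direction, passing neither in the main fit nor in the alternative. Of the values that passed in either, 0 changed direction. With DESeq2 12 values of named genes had no adjusted p. For genes by sort gate 13.3% passed, 25.7% with DESeq2, 8.96% with no replicate block, and 6.01%, 3.44%, 1.12% and 8.30% without day 26, 54, 100 and 125. Of these gate calls 97.7% were shared with DESeq2, 69.98% with limma on CPM, 64.6% with limma on TPM, 57.02% without the block, and 38.1%, 24.5%, 7.95% and 52.8% without days 26, 54, 100 and 125. For genes by day in DCX+ 0% passed, with 8.81% under DESeq2 and 0% to 0.0869% with 1 day left out. For genes by day in DCX- 0.0295% passed, with 14.2% under DESeq2, 0% under limma on CPM or TPM, 0.00591% with untransformed day, 0.323% without the stress-gene cluster and 0% to 0.0425% with 1 day left out. For genes whose slope differs between gates 0.00566% passed, with 3.53% under DESeq2, 0% under limma on CPM or TPM and without the lettered plates, and 0% to 0.0173% with 1 day left out. For genes by day in inhibitory-neuron-like cells 0% passed, with 9.26% under DESeq2 and 0% to 1.01% with 1 day left out. With 1 day left out a trend has 1 residual degree of freedom, and the omission itself lowers the number of samples. For the other changes the cause was not tested. With an estimated correlation 0 of the 11 lists called between the gates, 0 of 12 in DCX+, 0 of 12 in DCX− and 0 of 9 in the inhibitory-neuron-like cells stayed called. With fry the 11 lists between the gates stayed called except Notch and proneural (fry adjusted p = 0.0540) and astrocyte genes (0.0817). Hedgehog targets, not called by camera, had a fry adjusted p = 0.0368. Over the days fry called only ventral forebrain transcription factors in DCX+ (adjusted p = 0.0284) and no list in DCX−. In the inhibitory-neuron-like cells fry called only these factors (0.0157) and hypoxia and glycolysis genes (0.00177).

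The mean difference in share between the gates (percentage points) for inhibitory-neuron-like cells was 59.9 at resolution 0.5, 69.7 with TPM, 71.1 with 4000 genes and 68.2 without the marker genes, and 76.8 to 79.6 with 1 day left out. Their share of DCX+ cells at day 26 moved from 76.7% to 0.408% at resolution 0.5, 36.3% with TPM, 40.4% with 4000 genes and 36.3% without the marker genes. Without day 26, 54, 100 and 125 in turn, radial-glia-like cells reached -23.2 (main value -36.5), dividing cells -4.89, astrocyte-like cells -12.1, neurogenic progenitor-like cells -2.70 (main value -6.43) and oligodendrocyte-lineage-like cells 0.680 (main value 1.39) at the smallest. Dividing cells moved from -7.57 to -29.1 at resolution 0.5, -13.97 at resolution 2, -13.9 without the lettered plates, -10.5 with 4000 genes and -12.7 without the marker genes. Astrocyte-like cells stood at -14.5 at resolution 2 against -23.0. A mesenchymal-like cluster, absent otherwise, stood at -6.31 at resolution 2, -5.51 with 4000 genes or without the lettered plates and -5.80 without the marker genes. At resolution 0.5 neurogenic progenitor-like cells stood at -16.7 and radial-glia-like and oligodendrocyte-lineage-like cells at 0. The latter stood at 0 without the marker genes too, and with TPM neurogenic progenitor-like cells stood at 0 and radial-glia-like cells at -24.5. Neurogenic progenitor-like cells reversed to 2.57 without the marker genes and oligodendrocyte-lineage-like cells to -2.18 at resolution 2. The difference of unnamed clusters moved from -6.17 to -14.5 with TPM and -15.2 without day 26, and reversed to 23.9 at resolution 0.5, 1.21 with 4000 genes, 6.74 without the marker genes and 5.26 without day 125. The cause was not tested. With the lettered plates left out or the shares taken at resolution 2, the inhibitory-neuron-like difference stayed within its spread. The alternatives named here without marker genes or without the stress-gene cluster were chosen after the data were seen. Of the shares of subtype markers under the alternatives, 93.3% stayed within their interval. Cells were fewest at day 125, where a class share of 0 allows up to 3.75% of the 80 DCX+ cells and 4.11% of the 73 DCX− cells.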

Other observations

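The test of SST per cell was set before its result was seen. The other tests of explanations in this part were chosen after. MHC and interferon genes were lower in DCX+ than in DCX−, with 5 of 12 passing and 8 when adjusted over the list alone (camera adjusted p = 5.95e-07, and adjusted p = 0.121 with an estimated correlation). IFITM3, an antiviral membrane protein, was 23.8-fold lower, IFIT1 9.21-fold and HLA-B 3.61-fold. Over the days the list was higher in DCX+ (camera adjusted p = 0.000374, 5 higher and 1 lower of 11 adjusted over the list alone) and in DCX− (camera adjusted p = 5.45e-06, 6 of 12). With an estimated correlation these had adjusted p = 0.461 and adjusted p = 0.453. In the inhibitory-neuron-like cells the list was not called (camera adjusted p = 0.219, 2 higher and 2 lower of 10 adjusted over the list alone). Unfolded protein response genes were higher at later days in DCX+ (camera adjusted p = 0.000763, 4 of 10 adjusted over the list alone), in DCX− (camera adjusted p = 2.21e-08, 6 of 10) and in the inhibitory-neuron-like cells (camera adjusted p = 0.00098, 0 of 10). With an estimated correlation these had adjusted p = 0.461, 0.453 and 0.356. TRIB3, a stress-induced pseudokinase, stood at 3.61, 19.5, 57.96 and 164.4 CPM in DCX− at days 26, 54, 100 and 125, where the stress-gene cluster held 47.9% of cells at day 125. In the inhibitory-neuron-like cells it stood at 1.08, 16.7, 28.6 and 25.6 CPM. Between the gates this list was not called (camera adjusted p = 0.261), with HSPA5 2.42-fold lower and ASNS 1.63-fold higher in DCX+. Hypoxia and glycolysis genes were higher at later days in DCX+ (camera adjusted p = 2.94e-06, and adjusted p = 0.424 with an estimated correlation, 5 of 15 adjusted over the list alone). The same held in the inhibitory-neuron-like cells (camera adjusted p = 0.00023, and adjusted p = 0.283 with an estimated correlation, 5 of 15), and they were not called in DCX− (camera adjusted p = 0.0961) or between the gates (0.0737). ADM, adrenomedullin, stood at 0, 0.192, 10.0 and 18.4 CPM in DCX+. Immediate early and heat shock genes were higher at later days in DCX− (camera adjusted p = 0.00036, and adjusted p = 0.539 with an estimated correlation, 2 of 12 adjusted over the list alone), with ATF3 at 7.18, 3.72, 12.5 and 164.5 CPM. ATF3 is among the genes that led the stress-gene cluster, which held 47.9% of the cells of the only DCX− plate of day 125. The list was not called in DCX+ (camera adjusted p = 0.911), in the inhibitory-neuron-like cells (0.787) or between the gates (0.0994), where HSPB1 was 7.13-fold lower in DCX+. Ribosomal protein genes were lower at later days in DCX− (camera adjusted p = 0.000116, and adjusted p = 0.453 with an estimated correlation, 2 of 21 adjusted over the list alone), with RPL7 at 2767, 1638, 1192 and 793 CPM. They were also lower in the inhibitory-neuron-like cells (camera adjusted p = 0.0285, and adjusted p = 0.780 with an estimated correlation, 0 of 21). They were not called in DCX+ (camera adjusted p = 0.147) or between the gates (0.0852), where RPS6 was 1.67-fold lower.

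Choroid plexus and ependyma genes were lower in DCX+ (3 of 8, 5 when adjusted over the list alone, camera adjusted p = 0.0191, and adjusted p = 0.291 with an estimated correlation), with RSPH1, a protein of cilia, 6.89-fold lower. They were higher at later days in DCX− (camera adjusted p = 0.0399, and adjusted p = 0.539 with an estimated correlation, 1 of 8 adjusted over the list alone), where the folate receptor FOLR1 stood at 0.0848, 0.373, 4.89 and 5.68 CPM. Mesenchymal, vascular and blood genes were not called between the gates (camera adjusted p = 0.0818, 3 of 14 lower, 5 adjusted over the list alone). COL1A1 stood at 19.5, 0.00270, 0.186 and 105.8 CPM in DCX− and at 0.741, 0, 0 and 0 CPM in DCX+. Hedgehog targets were not called either (camera adjusted p = 0.0818, 2 of 10 lower, 5 adjusted over the list alone), with the co-receptor BOC 7.86-fold lower in DCX+. Excitatory cortical genes were not called between the gates (camera adjusted p = 0.755), where BCL11B, also found in inhibitory neurons, was 8.28-fold higher and LHX2 8.05-fold lower in DCX+. They were lower at later days in DCX− (camera adjusted p = 0.0479, and adjusted p = 0.453 with an estimated correlation, 2 of 7 adjusted over the list alone), with NEUROG1 at 10.1, 0, 0.469 and 0 CPM. Diencephalon to hindbrain genes were lower at later days in DCX− (camera adjusted p = 0.0386, and adjusted p = 0.453 with an estimated correlation, 4 of 8 adjusted over the list alone). They were not called between the gates (camera adjusted p = 0.477), where FOXB1 was at most 1.07 CPM. Pluripotency genes were lower at later days in DCX+ (camera adjusted p = 0.0147, and adjusted p = 0.461 with an estimated correlation, 3 of 8 adjusted over the list alone), with LIN28A at 43.96, 1.38, 1.22 and 2.63 CPM. They were not called in DCX− (camera adjusted p = 0.0511) or between the gates (0.755), where NANOG differed by -0.14 ± 0.38 on the log2 scale. The remaining lists were not called over the days. In uncalled lists median, mean and test could differ in sign. This held for excitatory, oligodendrocyte, diencephalon and pluripotency genes between the gates and for hedgehog, GABAergic, excitatory and diencephalon genes in DCX+. It also held for radial glia, hedgehog and GABAergic genes in DCX−, and choroid plexus, immediate early and diencephalon genes in the inhibitory-neuron-like cells.

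Astrocyte genes stood higher in the DCX+ sums at day 125 than earlier. Doublets of a neuron and an astrocyte are argued against by the DCX level of the 20 astrocyte-like DCX+ cells of days 100 and 125, whose median was 0.0930% of that of the inhibitory-neuron-like cells (0.633 against 680.6 CPM), although 15% of the 20 cells lay above 25% of it. Whether astrocyte-like cells that passed the DCX+ gate are the main source stays open. Without these cells the 14 genes of the list kept a median of 7.40% of their day 125 level (0% to 108.8%), but 12 of the 14 are markers by which the class was named, so their loss follows from the naming, and the other 2, SLC4A4 and ALDOC, kept 76.1% and 81.6%. A change within neurons stays untested.

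It was hypothesised that the lower SST level after day 54 reflects fewer SST cells at a like level per cell. Among inhibitory-neuron-like cells with SST detected, the median was 2413 CPM at day 54 (1971 to 2965), 623.8 CPM at day 100 (352.01 to 1013) and 396.7 CPM at day 125 (190.9 to 819.4). The last was 16.4% of the value of day 54, under the bound of 50% set beforehand for arguing against it. That bound took no account of the spread between samples. Each day was 1 sample and day 125 had 1 plate, and the intervals cover cells only. The class also lay mostly in other clusters at days 100 and 125 than at day 54, so the hypothesis stays open. A further hypothesis was that CRABP1 and TAC3 lie in the same cells at day 100. CRABP1 was detected in 82.6% of the cells with TAC3 (61.2 to 95.05) and in 50.5% of those without (43.7 to 57.2). The share was higher on 3 of 4 plates and lower on plate 17 (78.6% against 87.3%), which held 14 of the 23 cells with TAC3. Among cells without TAC3 the share ran from 21.3% to 87.3% over the plates, so the pooled shares also reflect which plates the cells came from, and the question stays open.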
